A study of Homo sapiens with 4 samples.

How the data were processed

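Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in the MCF7 line of estrogen receptor positive breast cancer cells. Cells carried a control small interfering RNA (siCtrl) or one against BAP18 (siBAP), and were given ethanol vehicle (EtOH) or estradiol (E2) for 1 h. Each of the 4 combinations had 1 library. The labels give no batch, date or library size.

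The authors deposited 1 list of intervals per library and no lists of pooled libraries. Per the labels' protocols, valid peaks were those within a false discovery rate of 0.01, and promoter peaks were defined by a centre from 5000 bp upstream to 100 bp downstream of a transcript start. The same text states a fold enrichment above 2 of an immunoprecipitate over input for binding sites of BAP18, which was not applied to these lists. Reads were processed with CASAVA 1.4 and placed on build hg38, per the submitters' processing notes. The peak caller, the aligner and the treatment of duplicate reads are not stated. Each deposited interval carries a fold enrichment, which is a ratio to the authors' local background, a p-value and a false discovery rate, and a pileup, which is a signal in stacked fragments, not scaled to depth, per the file headers and values.

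The deposited lists hold all intervals down to p-values near 0.05, and their false discovery rates run up to 1. The threshold of 0.01 was therefore applied to the deposited false discovery rate to define the peaks, on chromosomes 1 to 22 and X. Coordinates are 1-based and inclusive. No list of artefact-prone regions was removed here, so a peak with an extreme pileup is not shown to be an open site. Peaks were ranked by the false discovery rate, then the p-value, then the fold enrichment, within their own list only. Lists were compared by overlap of at least 1 bp. A peak of the treated or siBAP library with no overlapping peak in its reference library was counted as gained, and the reverse as lost. Listed at a lower strength means that only an interval with a false discovery rate above 0.01 overlapped, and not listed means that no deposited interval did, which is not a read count of 0.

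Depth was read from the commonest fold enrichment of intervals with a pileup of 1, which corresponds to a background pileup of 2 divided by the fold, minus 1. The Poisson tail of that background equals the p-value the authors gave to the same intervals (0.0209 in siCtrl cells with EtOH).

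Gene positions came from a table of assembly GRCh38.p14 that gives no strand, so start sites could not be told from ends. The promoter window of the labels was applied to both annotated ends of each gene, from 5000 bp outside to 100 bp inside, and is called the gene end. In peak counts and gene lists, peaks near a gene lay within 50 kb of either end. For a gene list, a peak or merged region near more than 1 of its genes was counted once for each gene. The intervals and the random lists do not allow for that. Peak classes used 38151 protein-coding and long noncoding genes, and gene lists used 19974 protein-coding genes. All 245 names in 10 gene lists matched. The lists hold estrogen-induced genes, estrogen-repressed genes, luminal identity genes, basal and mesenchymal genes, genes of immune cells, NURF, CTCF and cohesin genes, endocrine resistance genes, cell cycle genes, immediate early genes and housekeeping genes, and some genes stand in more than 1 list.

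With 1 library per group there is no replicate error, so conditions were not tested against each other and no p-value across peaks or genes is given. Shares carry exact Clopper-Pearson 95% intervals, which cover counting error only. Gene lists were set beside 10000 random lists of the same size, matched on the number of nearby peaks in deciles, and the percentile describes these libraries only. For all 4 libraries together, overlapping peaks were merged into regions. Regions listed in exactly 2 libraries were sorted into patterns that follow E2, follow siBAP, or cross both. The ratio of the geometric means of the concordant and crossed patterns is 1 when libraries detect each region independently. This also needs depth to scale the odds of detection by the same factor for all regions, which was not checked.

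Genes were named by rules written before the data were examined. Per comparison and direction, these were the 10 protein-coding genes nearest to the strongest peaks without a counterpart, then at most 5 genes per list whose gene end held a peak in 1 of the 2 libraries only, and always GREB1, TFF1, PGR, MYC, CCND1, XBP1, ESR1, GATA3, FOXA1, CTCF, BPTF and C17orf49. From the first rule the text gives examples, most of them with high pileups, and counts over all 10. Names chosen in another way are marked where they appear.

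Overlap, windows and percentiles were tested on simulated data. Overlap and window counts had 0 errors against direct counting. Of 200 random lists of 30 genes drawn from 19589 genes, 11 fell outside the central 95%. All 200 lists simulated to lose 40% of their peaks, against 20% elsewhere, fell below the percentile 2.5. The simulated loss did not depend on peak strength, as the loss in these libraries does. The simulation therefore does not show how the percentiles behave for lists whose peaks differ in strength, or for smaller losses. Alternatives written before the data were examined were a reciprocal overlap of 50%, the stronger part of each list, lists of equal length, windows of 500 bp around the centre, all sequences, gene ends of 1000 bp on both sides, and gene windows of 10 and 100 kb. Other alternatives, which include absence from the whole deposited list and leaving out a library or a gene, were added after seeing the data. A planned search for sequence motifs was not run because it needs a genome sequence. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.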

Results

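Open chromatin was mapped in MCF7 cells with control or BAP18 small interfering RNA, each with EtOH or with E2 for 1 h, with 1 library in each of the 4 groups. BAP18 is a chromatin protein found with NURF, a complex that moves nucleosomes and has BPTF as its large subunit. The design asks how estradiol changes accessibility within 1 h and whether BAP18 takes part in it. The siCtrl EtOH library had 96224 peaks, the siCtrl E2 library 100618, the siBAP EtOH library 98818 and the siBAP E2 library 97387. The background pileup was 0.220, 0.230, 0.233 and 0.154 in the same order, so that the siBAP E2 library stood at 0.700 of the siCtrl EtOH library. A pileup of 3 was enough for a peak in the siBAP E2 library, while the other libraries needed 4, and pileups are not scaled to depth. No group had replicates, and no difference below can be set against the spread between cultures.

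The gene of the knocked-down protein, C17orf49 (BACC1 in the gene table, chromosome 17, 7014782 to 7017520), carried a gene-end peak in all 4 libraries. Its pileup was 19 in siCtrl EtOH, 20 in siCtrl E2, 21 in siBAP EtOH and 16 in siBAP E2. A small interfering RNA acts on the transcript, so accessibility at the gene does not show whether the knockdown worked. BPTF and CTCF carried gene-end peaks in all 4 libraries as well. BPTF had pileups of 46, 38, 40 and 26, and CTCF, the main insulator protein, had 56, 59, 50 and 41, in the same order of libraries.

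The libraries shared most of their strong sites. Merging all peaks gave 145080 regions, of which 61387 (42.3%) were listed in all 4 libraries and 45285 (31.2%) in 1 library only. Of the 20000 strongest peaks of each library, between 0.11% and 0.475% had no counterpart in another library. Gene ends held 22.5% of the siCtrl EtOH peaks (95% interval 22.2 to 22.8), 22.5% of the siCtrl E2 peaks (22.2 to 22.7), 22.6% of the siBAP EtOH peaks (22.3 to 22.9) and 22.2% of the siBAP E2 peaks (21.9 to 22.5). Gene bodies held 49.2% to 49.7% and intergenic DNA 27.8% to 28.5%. Of 19974 protein-coding genes, 13773 had a gene-end peak in all 4 libraries and 3634 in no library.

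Estradiol in siCtrl cells asks for the normal early response. GREB1, a coactivator gene induced by estrogen, had 18 peaks within 50 kb of its ends with EtOH and 21 with E2, with 5 gained and 2 lost. ESR1, which encodes the estrogen receptor, went from 17 to 22 peaks, with 6 gained and 1 lost. XBP1, a luminal transcription factor gene, went from 6 to 8. TFF1, a classical estrogen target, went the other way, from 12 to 8, with 4 lost and 0 gained. MYC stayed at 9, CCND1 at 11 and CTCF at 14. PGR went from 7 to 6, GATA3 from 4 to 5, FOXA1 from 10 to 11, BPTF from 19 to 20, and C17orf49 stayed at 9.

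Across the genome, 23147 of the E2 peaks were gained (23.005%, 22.7 to 23.3), and 18975 of the EtOH peaks were lost (19.7%, 19.5 to 19.97). Nearly equal numbers were shared from either side, 77471 and 77249, so the excess of gained over lost peaks follows the lengths of the lists, here and in the other comparisons. The differing peaks were weak. The median pileup was 5 for gained peaks and 11 for shared peaks of the E2 library, and 5 against 10 for lost and shared peaks of the EtOH library. Of the gained peaks, 64.9% were listed at a lower strength with EtOH, and of the lost peaks 68.3% were listed at a lower strength with E2. The share found in the other library fell from 99.9% in the strongest of 20 strength bins of the E2 list to 34.8% in bin 18, and was 41.6% in the weakest. Gene ends held 14.6% of the gained peaks (14.2 to 15.1) against 24.8% of the shared peaks (24.5 to 25.1), so that the differing peaks lay away from gene ends more often than shared ones. Peak strength, which also differed, was not matched for this share, here or in the other comparisons.

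**Figure D1:**
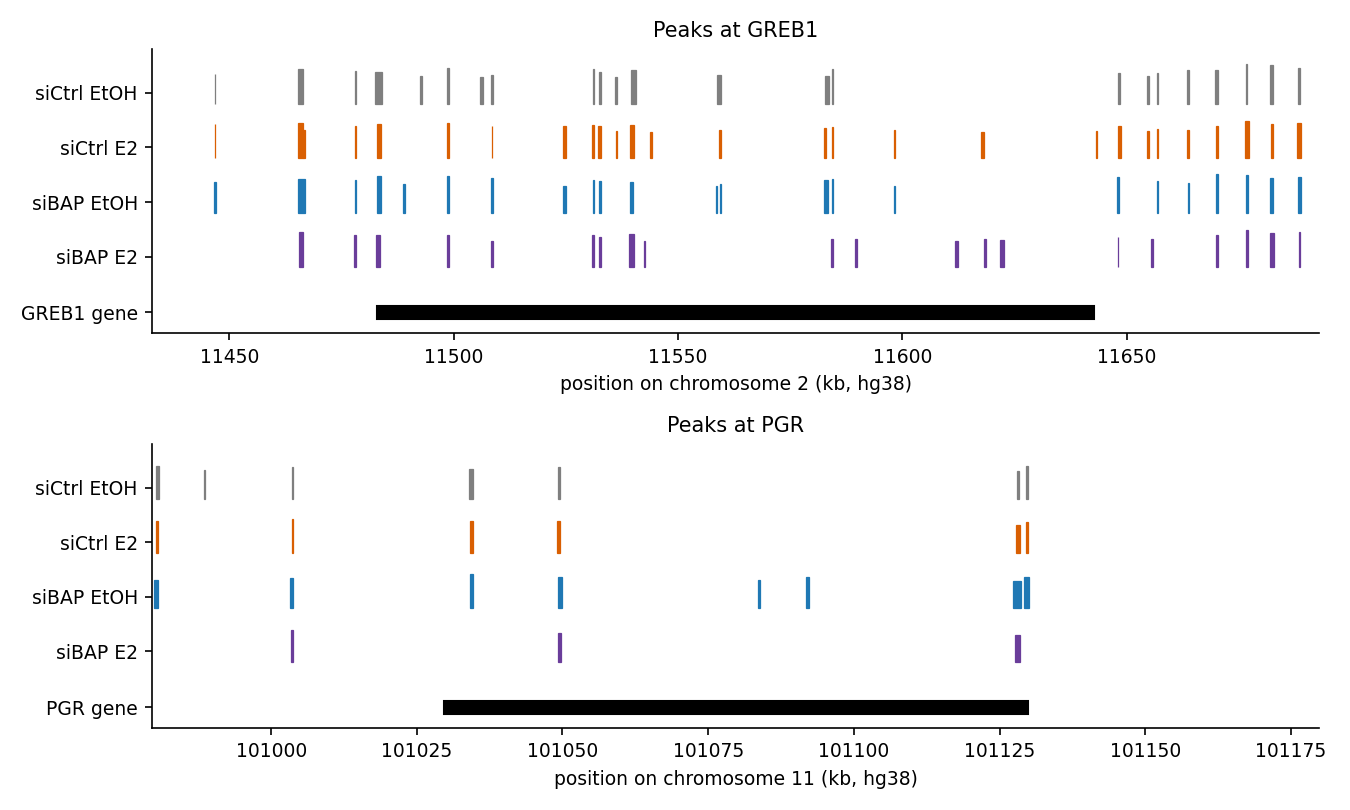
Peaks at GREB1 and PGR in the 4 libraries, with position on hg38 in kb on the horizontal axis, 1 lane per library, each peak drawn to scale in width, its height rising with the log2 of its fold enrichment, and the gene as a black bar. The drawn region at GREB1, with the whole gene body, holds 23, 27, 23 and 20 peaks in siCtrl EtOH, siCtrl E2, siBAP EtOH and siBAP E2, and that at PGR 7, 6, 8 and 3.

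Peaks near the 40 estrogen-induced genes were shared at a rate inside the range of random genes. Of 379 E2 peaks within 50 kb, 78.1% (73.6 to 82.2) were found with EtOH, at percentile 5.78 of random lists, whose median was 81.5%. Their strength alone, from the shares found in the 20 strength bins of the list, would give 76.5%, so the low percentile goes with weaker peaks near these genes. The same share was 80.2% for estrogen-repressed genes, 83.5% for luminal identity genes, 78.4% for basal and mesenchymal genes and 83.3% for genes of immune cells. It was 82.7% for NURF, CTCF and cohesin genes, 77.1% for endocrine resistance genes (percentile 4.53), 84.9% for cell cycle genes, 81.6% for immediate early genes and 84.8% for housekeeping genes. All 10 lists lay inside the central 95% of random lists in this direction. In the opposite direction 83.1% (78.8 to 86.9) of the EtOH peaks near estrogen-induced genes were found with E2.

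At the gene ends, 37 of the 40 estrogen-induced genes had a peak with EtOH and 37 with E2. Differences beyond peak edges were few. TP63, which encodes a basal transcription factor, had a gene-end peak with E2 (pileup 6) and an interval of pileup 2 below the threshold strength with EtOH. KRT17, a basal keratin gene, had pileups of 5 and 3, and PAK1, a kinase gene of the endocrine resistance list, 4 and 1. For RARA, RAPGEFL1, ALDOA and CSF1R, a peak that overlapped the one at the gene end was above the threshold strength in the other library and lay outside the window, so their differences came from peak edges. The strongest gained peaks included those near KIF5C, a kinesin gene (chromosome 2, 148881729 to 148881857, pileup 1054), LOC102724250 (pileup 3667 but a fold enrichment of 2.30), PPM1L (pileup 62), SULF2 (pileup 46), MYT1L (37) and RAE1 (33). Among the strongest lost peaks were those near PTPRT (26, at 183154 bp), ASB15 (20), ST20-MTHFS (20), SUCO (19) and EFNA5 (19, at 823357 bp). Of these 10 gained and 10 lost peaks, 8 in each direction were listed in 3 of the 4 libraries, which leaves siCtrl EtOH or siCtrl E2 as the library that differed. The KIF5C and RAE1 peaks were in the siCtrl E2 library alone. The KIF5C peak was 129 bp wide, and its pileup stood against a median of 9 among siCtrl E2 peaks. It is not shown to be an open site.

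**Figure D2:**
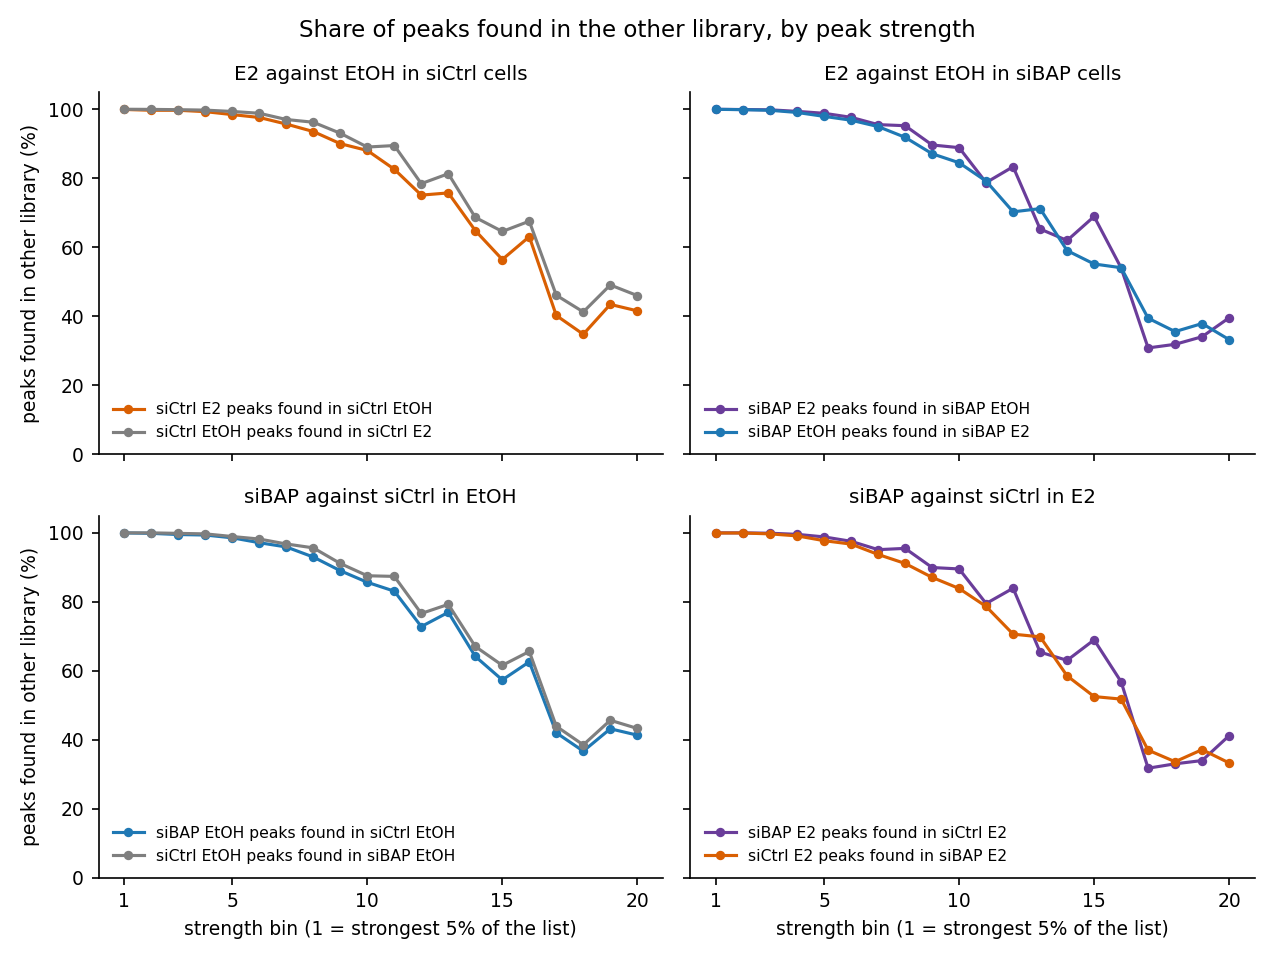
Share of peaks found in the other library of each comparison (vertical axis, percent) by strength bin of the list (horizontal axis, 20 bins, bin 1 the strongest), with 1 line per direction. In all 8 directions nearly every peak of the strongest bin was found, and the weakest bin of the siCtrl E2 list was found at 41.6% with EtOH.

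Estradiol in siBAP cells asks what the response was with siBAP. Here 10 of the 12 always-named genes had fewer peaks with E2 than with EtOH, in the library with the lowest background. The 40 estrogen-induced genes as a list did not follow them. Of these, 17 had more peaks with E2, 17 fewer and 6 as many, with 348 peaks with EtOH and 346 with E2. PGR, the progesterone receptor gene and an estrogen target, went from 8 to 3 peaks within 50 kb, with 5 lost and 0 gained. CTCF went from 16 to 10, GATA3 from 9 to 6, MYC from 11 to 8, BPTF from 18 to 15, GREB1 from 18 to 16, ESR1 from 21 to 19 and FOXA1 from 8 to 6. TFF1 went from 11 to 10 and XBP1 from 9 to 8. CCND1, the cyclin D1 gene, went from 13 to 14, and C17orf49 stayed at 8.

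Gained peaks numbered 23686 (24.3%, 24.1 to 24.6) and lost peaks 25352 (25.7%, 25.4 to 25.9), with a median pileup of 3 and 5 against 8 and 11 for shared peaks. Of the gained peaks 61.6%, and of the lost peaks 57.7%, were listed at a lower strength in the other library. Gene ends held 12.6% of gained peaks (12.2 to 13.1) and 15.5% of lost peaks (15.1 to 16.0).

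Of the estrogen-induced genes, 38 had a gene-end peak with EtOH and 34 with E2 in siBAP cells. PGR, SGK3, a kinase gene, IGFBP4, which encodes an insulin-like growth factor binding protein, and RAPGEFL1 lost it. PGR had a pileup of 7 with EtOH and 3 with E2, SGK3 had 11 and 5, and IGFBP4 6 and 2, and in all 3 genes the E2 interval was listed below the threshold strength. RAPGEFL1 differed by a peak edge. Over all protein-coding genes, 895 of 15126 (5.92%) lost the gene-end peak in this comparison, and 641 gained one. Other list genes that lost one were TP63, TAGLN, PAK1, CCNE2 and ESR1, and ESR1 had a gene-end peak (pileup 6) in siBAP EtOH only. There siCtrl EtOH listed an interval of pileup 4 below the threshold strength. The gene-end window covers only the outer annotated ends of ESR1 (chromosome 6, 151656672 to 152129619), so starts inside the gene are not covered. At CCNE2 the pileup was 15 with EtOH and 8 with E2. The siBAP E2 library listed a peak of pileup 50 at this gene outside the window, so the gene end is not shown to close. SMARCA1, which encodes a NURF ATPase, lost one by a peak edge. ZNF217 and MS4A1 gained one, at pileups of 6 and 3, as did CSF1R at 6, and ALDOA by a peak edge.

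Of the 10 lists, cell cycle genes had the highest share of EtOH peaks found with E2. Of 237 EtOH peaks near them 86.1% (81.0 to 90.2) were found, at percentile 99.8 of random lists (median 78.3%). Peak strength alone would give 82.8%. Genes of immune cells came next at 85.3% (percentile 97.1), inside the central 95%, and housekeeping genes stood at 83.4% (percentile 97.9). Within 10 kb the percentiles of cell cycle and housekeeping genes were 94.7 and 94.2, inside the central 95%. The estrogen-induced list stood at 79.3% (percentile 67.4), and at 80.1% (percentile 12.6) for E2 peaks found with EtOH. Peaks near NURF, CTCF and cohesin genes stood low, at 72.0% (64.1 to 79.0, percentile 3.95), where strength alone would give 76.6%, but at 83.7% (percentile 65.0) within 10 kb. For E2 peaks found with EtOH, basal and mesenchymal genes stood highest at 86.3%, with housekeeping genes at 85.9% and cell cycle genes at 85.8%. The strongest gained peaks included those near KCNJ3 (pileup 30), a potassium channel gene, OSBPL6 (21), LRRC30 (21) and PRR14 (21), and the strongest lost peaks near LARP1B (46), MARS1 (34), CCDC68 (29) and LTA4H (29). The KCNJ3 peak lay 405615 bp from the gene and was in siBAP E2 alone. The LRRC30 peak lay 53703 bp from the gene. It was listed in both E2 libraries and in neither EtOH library, with a pileup of 18 in siCtrl cells. In each direction 8 of the 10 peaks were listed in 3 of the 4 libraries.

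BAP18 knockdown without estradiol asks what the protein does at rest. Of the 12 always-named genes 7 had more peaks with siBAP and 4 had fewer, in a library that listed 2594 more peaks. Of the 20 luminal identity genes 10 had more, 6 fewer and 4 as many. GATA3, a luminal transcription factor gene, went from 4 to 9 peaks within 50 kb, with 6 gained and 0 lost, and ESR1 from 17 to 21, with 8 gained and 3 lost. XBP1 went from 6 to 9, MYC from 9 to 11, CCND1 from 11 to 13, CTCF from 14 to 16 and PGR from 7 to 8. GREB1 stayed at 18. FOXA1 went from 10 to 8, TFF1 from 12 to 11, BPTF from 19 to 18 and C17orf49 from 9 to 8.

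Gained peaks numbered 22820 (23.1%, 22.8 to 23.4) and lost peaks 20373 (21.2%, 20.9 to 21.4). Their median pileup was 5 in both directions, against 11 and 10 for shared peaks, and 63.5% and 68.7% were listed at a lower strength in the other library. Gene ends held 14.5% of gained peaks (14.1 to 15.0) and 14.0% of lost peaks (13.5 to 14.5). Gene-end peaks were gained at KRT17 (pileup 7 against 3), TP63 (4 against 2), TAGLN (4 against 3), PAK1 (4 against 1) and ESR1 (6 against 4), each listed at a lower strength in siCtrl cells. CSF1R lost a weak one (4 against 3). RARA, ALDOA and SMARCA1 differed by peak edges. Over all protein-coding genes, 687 gained a gene-end peak and 604 lost one.

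Peaks near NURF, CTCF and cohesin genes were the least shared list in the siCtrl direction. Of 155 siCtrl peaks near them, 77.4% (70.0 to 83.7) were found in siBAP cells, at percentile 2.46 of random lists (median 83.7%), where strength alone would give 80.0%, and at percentile 47.2 within 10 kb, and in the opposite direction 81.3% were (percentile 43.3). Cell cycle genes stood at 88.6% (percentile 98.2) and, in the opposite direction, at 87.3% (percentile 98.9), where strength alone would give 85.7% and 84.8%. With a 100 kb window the call in the opposite direction ended. Estrogen-induced genes stood at 84.3% (percentile 59.0) and 84.8% (percentile 92.0). The strongest lost peak lay in PCBD2 (chromosome 5 from 134924140, pileup 801), which was at 769 in siCtrl E2 and not listed in either siBAP library. It was 238 bp wide, in a library with a median pileup of 8, and is not shown to be an open site. Other lost peaks lay near HINT3 (pileup 30), CWH43 (21, at 220004 bp), UBE2E3 (20) and KCNJ15 (20). Gained peaks included those near PPM1L (70), METTL2A (58), NEK10 (34) and CBFA2T3 (32). The peak at LOC102724250, with a pileup of 3691 but a fold enrichment of 2.29, was also gained by this rule. Of the strongest peaks, 9 of 10 gained and 8 of 10 lost were listed in 3 of the 4 libraries.

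BAP18 knockdown with estradiol asks whether sites open under estradiol need the protein. Of the 12 always-named genes 8 had fewer peaks with siBAP, again in the library with the lowest background. Of the 40 estrogen-induced genes 18 had fewer, 12 more and 10 as many. GREB1 went from 21 to 16, with 8 lost and 3 gained, FOXA1 from 11 to 6, with 5 lost and 0 gained, and BPTF from 20 to 15, with 6 lost and 1 gained. CTCF went from 14 to 10, PGR from 6 to 3, ESR1 from 22 to 19, MYC from 9 to 8 and C17orf49 from 9 to 8. XBP1 stayed at 8, GATA3 went from 5 to 6, TFF1 from 8 to 10 and CCND1 from 11 to 14.

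Gained peaks numbered 23202 (23.8%, 23.6 to 24.1) and lost peaks 26563 (26.4%, 26.1 to 26.7), with a median pileup of 3 and 5 against 8 and 11 for shared peaks. Of them 60.5% and 58.7% were listed at a lower strength in the other library. Gene ends held 12.8% of gained peaks (12.3 to 13.2) and 15.7% of lost peaks (15.2 to 16.1). SGK3, PGR and IGFBP4 lost their gene-end peaks, with pileups of 16, 9 and 8 in siCtrl cells against intervals of 5, 3 and 2 below the threshold strength in siBAP cells. That is 3 of the 37 estrogen-induced genes with a gene-end peak (8.11%), against 904 of 15149 protein-coding genes (5.97%). TP63 and PAK1 lost theirs too. CCNE2 lost its own by a peak edge, since the overlapping peak had a pileup of 85 in siCtrl and 50 in siBAP cells. ZNF217, MS4A1 and CSF1R gained one, and ALDOA did by a peak edge.

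Of 379 siCtrl peaks near estrogen-induced genes, 74.1% (69.4 to 78.5) were found with siBAP, at percentile 6.18 of random lists (median 77.6%), where strength alone would give 72.5%. Cell cycle genes stood at 85.3% (80.1 to 89.5), at percentile 99.7 (88.7 within 10 kb), where strength alone would give 81.1%. Of the strongest lost peaks, those near KIF5C (pileup 1054), CD74 (42), which encodes the invariant chain of MHC class II, and RAE1 (33) were in siCtrl E2 alone. An intragenic peak of BPTF (chromosome 17, 67833921 to 67834418) had pileups of 20, 23 and 11 in the other libraries and was not listed in siBAP E2. LARP1B had a lost peak of pileup 44, and the PCBD2 peak of pileup 769 was lost as well. Gained peaks were near KCNJ3 (30, at 405615 bp), PTPRT (17, at 183384 bp), SAMD4A (15) and KDM4C (14, at 226532 bp). Here 9 of 10 gained and 6 of 10 lost peaks were listed in 3 of the 4 libraries.

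**Figure D3:**
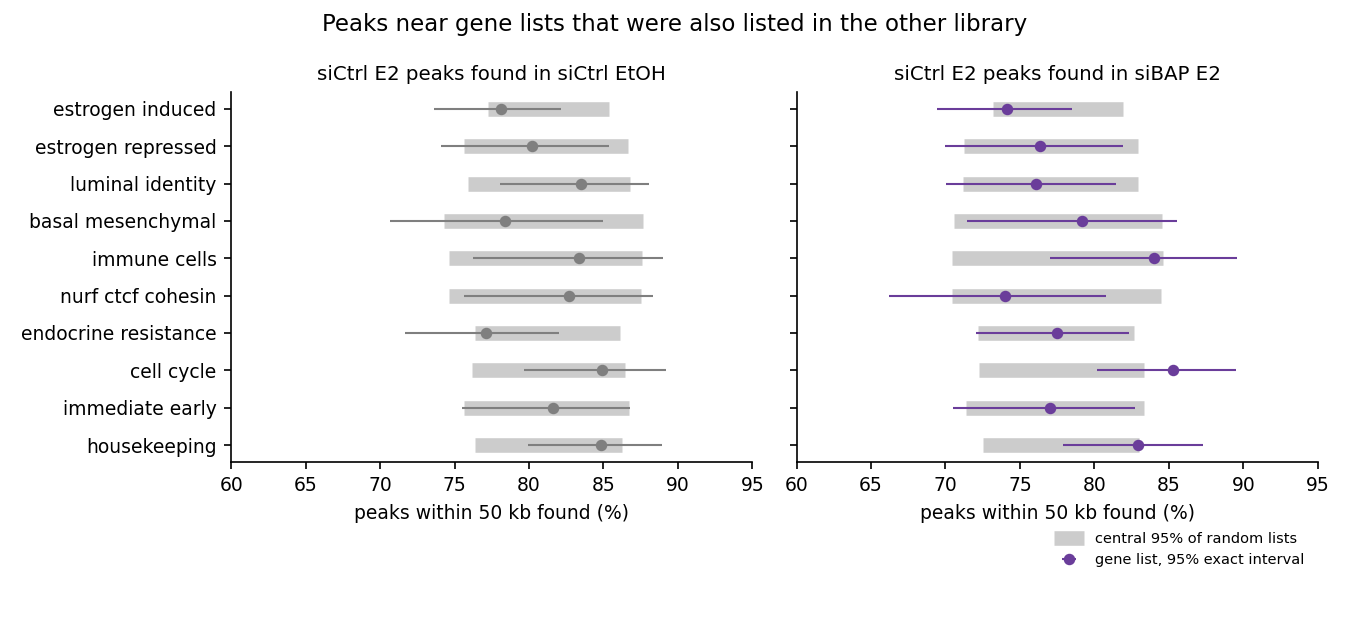
Share of siCtrl E2 peaks within 50 kb of the genes of 10 lists that were found in siCtrl EtOH (left) and in siBAP E2 (right), on a horizontal axis in percent that starts at 60. Points are the lists with exact 95% intervals, and grey bars are the central 95% of 10000 random lists. Estrogen-induced genes lie inside the grey bars at 78.1% and 74.1%, where strength alone would give 76.5% and 72.5%. Cell cycle genes lie above the grey bar on the right at 85.3%, where strength alone would give 81.1%.

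Over the 4 comparisons and both directions, 6 of the 80 list shares lay outside the central 95% of random lists, 5 above and 1 below. Of the 5 above, 4 were cell cycle genes and 1 was housekeeping genes, and the 1 below was the NURF, CTCF and cohesin list. Random lists would give 4 of 80 by construction, and the 80 shares reuse the same 4 libraries. The estrogen-induced list ranged from percentile 5.78 to percentile 92.0.

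The 4 libraries together ask whether sites that differ with E2 do so in both backgrounds. Of the 23147 peaks gained with E2 in siCtrl cells, 34.1% (33.5 to 34.7) were found in siBAP E2 and 39.1% (38.5 to 39.7) in siBAP EtOH, the library without estradiol. Peaks of the same strength common to both siCtrl libraries were found at 63.6% and 70.9%. Common peaks are chosen for being found in another library, so a lower share for gained or lost peaks is expected by construction. Of the 18975 peaks lost with E2, 31.6% were found in siBAP E2 and 35.6% in siBAP EtOH. Of the peaks gained with E2 in siBAP cells, 29.8% were found in siCtrl E2 and 28.1% in siCtrl EtOH, and of those lost 44.6% and 41.5%. Peaks common to both siBAP libraries at the strength of the gained ones were found at 74.8% and 71.1%. In all 4 sets the share was higher in the library that listed more peaks, with or without estradiol.

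Regions listed in exactly 2 libraries gave the same comparison with no reference library. Both E2 libraries alone held 2940 regions and both EtOH libraries alone 3241, while the crossed patterns held 2534 and 4024. The ratio of E2 patterns to crossed patterns was 0.967 (counting interval 0.933 to 1.00). Both siBAP libraries alone held 3077 regions and both siCtrl libraries alone 3996, a ratio of 1.098 (1.06 to 1.14). A ratio of 1 is what independent detection gives if depth scales the odds of detection alike for all regions.

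**Figure D4:**
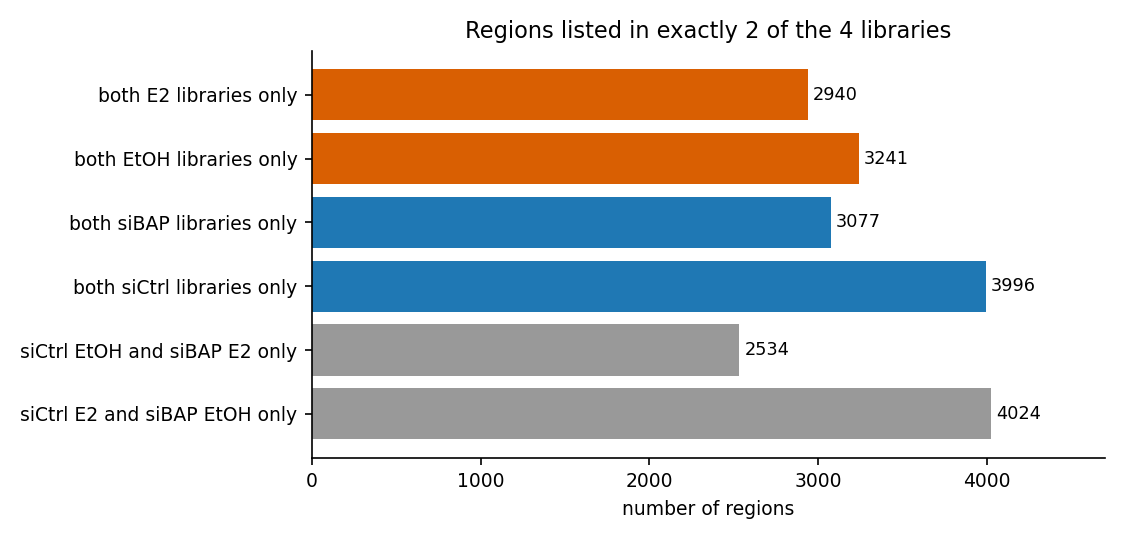
Number of regions (horizontal axis) listed in exactly 2 of the 4 libraries, for each of the 6 pairs, with E2 pairs in orange, siBAP pairs in blue and crossed pairs in grey. The crossed pairs, at 2534 and 4024, bracket the pairs that follow E2 or siBAP.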

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

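All tests of the explanations weighed here were chosen after the result was seen. The number of peaks changed with E2 in opposite directions in the 2 backgrounds, by 4394 in siCtrl cells and -1431 in siBAP cells. Likewise siBAP against siCtrl differed by 2594 peaks with EtOH and by -3231 with E2. With 1 library per group, none of the differences in this part was tested. The E2 change was also opposite within 50 kb of 6 named genes, given here for siCtrl and then siBAP cells. It was 3 and -2 peaks at GREB1, 2 and -1 at XBP1, 5 and -2 at ESR1, 1 and -3 at GATA3, 1 and -2 at FOXA1, and 1 and -3 at BPTF. The siBAP change was opposite at 5 genes, given for EtOH and then E2. It was -1 and 2 at TFF1, 1 and -3 at PGR, 2 and -1 at MYC, 4 and -3 at ESR1, and 2 and -4 at CTCF.

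A loss of the E2 response at estrogen target genes in siBAP cells would be a biological explanation. The ratio of E2 to EtOH peak numbers in siBAP cells over that in siCtrl cells was 0.918 near all protein-coding genes together. It was 0.934 near estrogen-induced genes, at percentile 68.2 of random lists, which argues against a loss that is stronger there than elsewhere. The lower count near genes in general occurred in the library with the lowest background, 0.700 of the siCtrl EtOH library, and whether the background caused it was not tested. A loss at estrogen target genes, a change of accessibility that affects all genes alike, and a difference between cultures stay open.

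Peaks on unplaced and other sequences, which the comparisons of the report did not use, numbered 421 in siCtrl EtOH and 434 in siBAP EtOH, which is above that control. They numbered 404 in siCtrl E2 and 387 in siBAP E2.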

How the results depend on the processing

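Counts of gained and lost peaks stayed within 1.5 times with lists of equal length, with 500 bp around the centre and with all sequences. They moved with the overlap and the strength. In the order of the 4 comparisons of the report, gained then lost, a reciprocal overlap of 50% gave 44392, 39998, 46446, 47877, 44260, 41666, 45814 and 49045. The stronger part of each list against the whole other list gave 1909, 1292, 1709, 2380, 2083, 1556, 1666 and 2571, which is fewer by construction. Absence from the whole deposited list, added after seeing the data, gave 8128, 6010, 9092, 10717, 8324, 6371, 9168 and 10959. Every deposited interval, also added, gave 547763, 536388, 418549, 597255, 556209, 535357, 420421 and 589928. In these 4 settings the larger of the gained and lost counts was the same as in the main count in all 4 comparisons. The longer list of each comparison also stayed the longer one, so this says little about a direction. Lists of equal length gave 20567, 20543, 23685, 23974, 21269, 21287, 23758 and 24013, where gained and lost peaks are nearly equal by construction.

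The share of E2-gained peaks found in siBAP E2 was 28.5% with reciprocal overlap, 44.3% in the stronger part of each list and 35.3% with lists of equal length. Its difference from common peaks of the same strength, -29.5 percentage points, was -21.8 with reciprocal overlap, -25.9 in the stronger part and -51.3 with no strength bins. A negative difference is expected from how the sets are chosen. Gene ends of 1000 bp on both sides held 18.0%, 17.5%, 17.7% and 17.4% of peaks in siCtrl EtOH, siCtrl E2, siBAP EtOH and siBAP E2. With a 10 kb window, the share shared near estrogen-repressed genes moved to 89.4% (siCtrl EtOH in siCtrl E2), 90.9% (siBAP E2 in siBAP EtOH), 90.3% (siBAP EtOH in siCtrl EtOH), 95.5% (siCtrl EtOH in siBAP EtOH) and 89.4% (siBAP E2 in siCtrl E2). The other 11 shares of the estrogen lists stayed within their intervals, and so did all 16 with a 100 kb window and all 16 with lists of equal length. For the other lists 26 of 64 shares rose beyond their intervals at 10 kb, and none moved under the other 2 settings. Lists outside the central 95% of random lists numbered 6 of 80, and 4 at 10 kb, 12 at 100 kb and 8 with lists of equal length, and 2, 4 and 5 of the original 6 were among them. At 10 kb the calls that ended were cell cycle genes for siBAP EtOH in siBAP E2 (percentile 94.7) and for siCtrl E2 in siBAP E2 (88.7), housekeeping genes for siBAP EtOH in siBAP E2 (94.2), and NURF, CTCF and cohesin genes for siCtrl EtOH in siBAP EtOH (47.2). At 100 kb they were cell cycle genes for siBAP EtOH in siCtrl EtOH (96.1) and the housekeeping call (97.1), and with lists of equal length the NURF, CTCF and cohesin call (3.99). The cause of these moves was not tested.

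Of the pattern ratios, siBAP moved to 1.04 (0.944 to 1.15) when absence meant the whole deposited list, and was 1.11 both at p below 1e-06 and with lists of equal length. The E2 ratio was 0.939, 0.987 and 0.980 in the same settings, all added after seeing the data. Without the siBAP E2 library, 68179 regions were listed in all 3 others. The motif alternatives were not run, because they need a genome sequence. No paired analysis was run, since each comparison held a single pair and its result came from no test. An additive fit over the 4 libraries was not run. Depth limits these lists to a pileup of 3 or 4, at which a site missing from a list is not shown to be closed.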

Other observations

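The tests on sampling and on narrow peaks in this part were chosen after the result was seen, and the others were written before. Regions listed in both E2 libraries and in neither EtOH library were more frequent near estrogen-induced genes than near most random lists of genes. Of 488 regions within 50 kb of these genes, 16 (3.28%, 1.89 to 5.27) had this pattern, at percentile 99.2 of random lists, whose median was 1.66%. Among all merged regions the share was 2.03%, inside that interval. The random lists were not matched on peak strength. The 16 regions lay near 12 genes. GREB1 had 1 inside the gene (chromosome 2, 11617459 to 11618552), with pileups of 7 and 8 with E2 in siCtrl and siBAP cells, a pileup of 2 in siCtrl EtOH and no interval in siBAP EtOH. XBP1 had 1 (chromosome 22, 28792791 to 28793337) with a pileup of 6 in both E2 libraries, none in siCtrl EtOH and 3 in siBAP EtOH. ADCY9 had 3, ELOVL2 and TPD52L1 had 2 each, and OLFM1, CXCL12, CCND1, HSPB8, FOS, IGFBP4 and NRIP1 had 1 each. These names were chosen after their values were seen.

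The prediction that such regions lie near estrogen-induced genes was met at 50 kb, by regions with pileups of at most 9. For 1 region each of ELOVL2 and ADCY9 the pileup was 3 in both siBAP libraries, which was enough for a peak in siBAP E2 only. In siCtrl cells the regions of CXCL12 and CCND1 and another of ADCY9 had a pileup of 3 with EtOH and 4 with E2, and that of FOS 7 and 9. The result was 1 of 40 combinations of list and pattern, and it was the 1 outside the central 95% of random lists. The percentile was 95.5 within 10 kb, 84.8 within 100 kb and 98.2 with lists of equal length (14 of 475 regions). At 50 kb it was 94.9 without ADCY9, 96.4 without ELOVL2 and 97.2 without TPD52L1, so the call rests on single genes. Regions in both siCtrl libraries and in neither siBAP library were not more frequent near the same genes, at percentile 39.97 with 11 of 488 regions.

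For the bulk of gained and lost peaks, the tables argue against sites that estradiol opens or closes in both backgrounds as the main source. The ratio of E2 patterns to crossed patterns was 0.967 (0.933 to 1.00), below the bound of 1.1 set beforehand. In simulated libraries of the same depths, over the same 145080 regions, the mean E2 ratio was 0.999 with no change, 1.03 with 1000 regions changed by 3-fold and 1.14 with 4000. The simulation took each region's rate from listed peaks only and called peaks at a fixed pileup per library, unlike the deposited lists. How many changed sites would raise the ratio in these data is therefore not known, and smaller numbers of changed sites stay open. For siBAP the ratio of 1.098 (1.06 to 1.14) lies above 1 and above the simulated ratios with no change, 0.973 to 1.06 in 20 draws. The simulated mean was 1.03 with 1000 changed regions and 1.15 with 4000. When absence meant the whole deposited list it was 1.04 (0.944 to 1.15), which includes 1. The main interval spans the bound of 1.1, and a difference between the siRNA cultures other than BAP18 would give the same pattern, so a cause in the knockdown stays open. Independent sampling of weak peaks near the threshold as the only source stays open as well. It needs ratios of 1 if depth scales the odds of detection alike, which the siBAP ratio meets by only 1 of these definitions.

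Some strong peaks were missing from 1 library. The pileup used here to call a peak strong was not scaled to depth. For siBAP E2 it was asked only of libraries with a higher background, so its count cannot be compared with the others. Of peaks with a pileup of at least 10 in the other 3 libraries, 141 of 27102 were not listed in siCtrl EtOH, 61 of 26306 in siCtrl E2, 69 of 26361 in siBAP EtOH and 252 of 32716 in siBAP E2. Their median width elsewhere was 278, 231, 277 and 294 bp, which is 0.509, 0.437, 0.534 and 0.552 of that of listed peaks with the same pileup. The shortest listed interval was 132, 127, 127 and 124 bp, in the same order. A minimum length set per library is a candidate explanation where an interval elsewhere was under this minimum. That was so for 10 of the 141 (7.09%) and 4 of the 69 (5.80%), and for 0 in both E2 libraries. The siBAP E2 minimum is the lowest of the 4, so no other result was possible there. For siCtrl E2 and siBAP EtOH only intervals of siBAP E2 could count, so low shares there say little. The width such a site would have had in the library that lacks it is not known, so the explanation stays open for the rest. The peak at LOC102724250 was 128 bp wide in siCtrl E2 and that at PPM1L 130 bp, both under the minimum of siCtrl EtOH. The KIF5C, PCBD2, RAE1 and CD74 peaks are not covered by this test, since fewer than 3 libraries listed them.

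Peaks were densest in a few 5 Mb windows. Chromosome 20 from 50000001 held 426 peaks on average over the 4 libraries, 2.63 times the median window, and chromosome 17 from 60000001 held 418. Parts of both chromosomes are known to be amplified in MCF7 cells.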
